A study of Danio rerio with 24 samples.

How the data were processed

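The samples were intestines dissected from zebrafish larvae of the AB wild-type background that carried a cldn15la GFP transgene, taken at 5, 7 and 9 days post fertilization (dpf). The fish were kept at 28.5 °C with 14 hours of light and 10 hours of dark, and the labels list rotifers, Artemia and a dry feed as food. RNA was sequenced from pools of 10 intestines as total RNA depleted of ribosomal RNA, with 3 libraries per age. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for H3K4me3, a histone mark of active promoters, and for H3K27me3, the mark placed by Polycomb repressive complex, with 2 libraries per age and mark from pools of 25 intestines. Each age had 1 input library, sequenced without an antibody, from 5 intestines. The labels do not say whether the pools of an age came from separate clutches or days, so each p value measures the spread between these pools, part of which may be technical.

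The RNA values were deposited as a signal: the authors divided the read count of each gene by 1 size factor per library, so the values are normalized read counts. Per the submitters' processing notes the reads were aligned to GRCz10 with STAR 2.5.2b and normalized with DESeq2 1.16.1. Multiplying each column by its own factor recovered whole reads for 100% of values within a tolerance of 1e-06, and size factors recomputed from those reads by the median of ratios equalled those of the authors. The table held 30263 genes and 0% of the reads lay outside named genes. The gene symbols are those of the deposited table, and 26065 of its 30263 identifiers matched the table of gene names used as a reference. Total reads per library ran from 7014333 to 14327144, and 3 reads, the limit that a count of 0 allows, came to 0.209 to 0.428 RPM (reads scaled to a library total of 1e+06). Such limits and the intervals given cover counting error only.

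The peak lists were deposited per library. Per the submitters' processing notes reads were aligned to GRCz10 with BWA 0.7.15, handled with Picard, and peaks were called with MACS2 2.1.1. Each deposited peak has a score, which the values show to be 10 times the -log10 of its q value, rounded down. It also has a fold enrichment by the authors, a ratio of the peak over its local background, and the deposited -log10 p and -log10 q of the peak. The notes do not say which control or threshold was used, and the sequencing depth of the ChIP libraries is unknown here, so no interval that needs a depth is given for peaks. Positions are given on GRCz10 and counted from 1.

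Genes with a value of 10 or more in at least 3 of the 9 libraries were tested, which left 24298. The test was limma 3.58.1 with a mean-variance trend and robust variance estimates on log2(value + 1), with all 9 libraries in 1 fit, and Benjamini-Hochberg adjustment within each contrast. A gene passed at an adjusted p under 0.05. The contrasts were 7 against 5, 9 against 7 and 9 against 5 dpf, and the difference of the 2 steps (7 to 9 dpf minus 5 to 7 dpf), which tests whether the steps differ. Fold changes rest on values with 1 added, which understates the change of weakly expressed genes. A replicate block was tried only as an alternative. The correlations of same-number libraries, after subtraction of age means, ran from -0.42 to 0.47, and only 1 of the 9 libraries correlated best with its own number. The numbers were not read as shared days, although these correlations cannot exclude a pairing.

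The gene lists, 31 in all, were fixed before the data were examined: lipid absorption and lipoproteins, brush border digestion and nutrient transport, lysosome-rich enterocyte, bile acid and xenobiotic handling, goblet cell, enteroendocrine cell, intestinal transcription factor and Notch, cell proliferation, exocrine pancreas, pancreatic islet, liver, smooth muscle and mesenchyme, enteric neuron and glia, myeloid leukocyte, lymphoid cell, intestinal inflammation and antimicrobial defence, cholesterol and fatty acid synthesis, fasting and fatty acid oxidation, Polycomb group and H3K27 demethylase, H3K4 methyltransferase complexes and demethylases, Hox genes, developmental transcription factors of other organs, skeletal muscle, epidermis and pigment cell, erythrocyte, kidney, swim bladder and heart, circadian clock, immediate early and heat shock, endoplasmic reticulum chaperones, mitochondrially encoded genes, and cytosolic ribosomal proteins. Ribosomal S6 kinase genes, whose names begin like those of ribosomal proteins, were left out of the last. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation; adjusted p values of lists are over the 31 lists of a contrast. Counts of members are given over all genes tested and, where named so, adjusted over the list alone.

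Named genes followed a rule fixed with the lists. For each age contrast it takes the 10 largest rises and the 10 largest falls among genes that passed, had a symbol that is not a clone name, had all 3 values of one age above all 3 of the other, and had a mean of at least 100 at the higher age. From each list it takes up to 4 members, those with the largest rises and falls past the threshold from 5 to 9 dpf, or the members with the highest mean where none passed. It adds ezh2, suz12a, suz12b, eed, kdm6ba, kdm6bb, cldn15la and hoxb13a. Genes outside the rule are examples of a list, chosen after their values were seen. Genes with near-identical copies, such as those of mfap4 and the histones, may share reads, so the division of reads between copies is uncertain.

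Touching peaks of the 6 libraries of a mark were merged into regions. A region was gained between 2 ages when both libraries of the later age and neither of the earlier age had a peak in it by at least 1 base, and lost when the reverse held. Overlap of peak lists was measured as the Jaccard index of covered bases. Regions with both marks were counted by age and set beside 100 circular shifts of the H3K27me3 regions along their chromosomes. Peak numbers were compared by exact permutation of libraries, for which 2 against 2 libraries allow no p below 0.333.

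The procedure was tested on simulated data with 24298 genes for 9 against 5 dpf. limma found 46% of 100 planted 2-fold changes and 90% of 100 planted 4-fold changes, with 14 calls among unchanged genes. edgeR 4.0.16 found 47% and 89% with 16 such calls, and DESeq2 1.42.0 found 47% and 88% with 24. camera gave the planted list an adjusted p of 4.55e-15 with the preset and 0.0168 with an estimated correlation, and called 0 of the other 30 lists at either setting. The simulated genes were drawn independently of each other. The simulation therefore does not test the preset for lists whose members move together. In the data the estimated correlation of the ribosomal protein list was 0.937. In 1000 simulated regions for 5 to 9 dpf, 95.8% of 120 planted gains and 97.5% of 80 planted losses were found. Those regions were well separated and few of their peaks were missed. In the data 76.5% of H3K4me3 and 27.9% of H3K27me3 regions lay in all 6 libraries, so these shares do not carry over to the deposited lists.

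The alternatives for RNA were other pseudocounts and filters, TMM and quantile scaling, the replicate block, edgeR and DESeq2 on the recovered reads, a 2-fold minimum, a fit without robust estimates, a fit with only the ages compared, and each library left out. For peaks they were stricter scores, an equal number of peaks per library, stricter overlap, merging within 1000 bases, removal of input peaks, and each library left out. Cyclic loess scaling and the removal of 3 libraries together were chosen after seeing the data. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The comparison of marks at annotated promoters with expression needs gene positions on GRCz10, which were not used here, so no region is given a gene name.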

Results

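The data are gene expression and 2 histone marks in the zebrafish larval intestine at 5, 7 and 9 dpf, the days around and after first feeding. RNA came from 9 libraries, 3 per age, named here by age and number, such as 9dpf_2. The 5 dpf libraries 1 to 3 held 7438866, 7014333 and 11721671 reads, the 7 dpf libraries 12046289, 8643185 and 12836717, and the 9 dpf libraries 9974251, 14327144 and 11007442. Between 28869 and 29464 genes had a read in a library. The most abundant transcript, named Metazoa_SRP, an RNA of the signal recognition particle, held 7.66% of all reads. The apolipoprotein B gene apobb.1 held 4.27%, and mitochondrially encoded genes held 2.05% to 4.07% of the reads of a library. Reads of odorant receptor genes, which belong to the olfactory lining, came to 408 RPM in 5dpf_2 and 215 RPM in 7dpf_2, and to 103 to 212 RPM in the others. ChIP-seq came from 12 libraries, 2 per age for each of H3K4me3 and H3K27me3, with 1 input library per age. Values are normalized read counts given as mean ± SD over n = 3 pools per age, and adjusted p values of genes are from limma.

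The comparison of 9 with 5 dpf asks what differed over the whole span. Genes of lipoprotein assembly were among the largest rises. apoba (ENSDARG00000042780), an apolipoprotein B that forms the core of lipoprotein particles, rose 40.5-fold (log2 5.34, SE 0.32, adjusted p = 5.30e-10), from 524 ± 281 to 19763 ± 4049. apoc1 (ENSDARG00000092170) rose 17.2-fold, from 942 ± 282 to 16033 ± 4197 (adjusted p = 9.59e-09). apoa1a (ENSDARG00000012076), the main protein of high density lipoprotein, rose 9.23-fold, from 10402 ± 2584 to 95849 ± 24475 (adjusted p = 2.38e-06). The largest rise was that of mt2 (ENSDARG00000041623), a metallothionein that binds zinc and copper, 57.5-fold from 39.2 ± 14.9 to 2271 ± 619 (adjusted p = 6.32e-07). The falls were smaller. miox (ENSDARG00000002764), the oxygenase that begins the breakdown of myo-inositol, fell 6.66-fold from 228 ± 57.2 to 33.6 ± 9.31 (adjusted p = 9.63e-08). The keratin gene krt15 (ENSDARG00000036840) fell 6.59-fold from 1687 ± 452 to 251 ± 40.7 (adjusted p = 2.08e-07).

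Other large rises from 5 to 9 dpf were those of a lactase-like gene named LCT (1 of many), 19.7-fold to 7288 ± 2435, and of the malic enzyme me1, 12.4-fold to 878 ± 134. The nuclear receptor nr0b2a, a target of the bile acid receptor, rose 11.5-fold to 4211 ± 1848, and the sulfate transporter slc13a1 rose 9.47-fold to 2959 ± 503. A pair of genes named MFAP4 (1 of many) rose 13.1-fold and 9.20-fold, and reads shared among their near-identical copies were not resolved. The other falls of the first 10 ran from 3.81-fold to 5.78-fold, with adjusted p between 6.97e-07 and 0.00907. They were those of the transcription factors jdp2b and klf4, the membrane protein gene mal, the deiodinase dio3b that inactivates thyroid hormone, the collagen receptor ddr2b, the sodium and proton exchanger slc9a3.2, the methyltransferase bhmt and the Wnt antagonist sfrp5.

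Of the 24298 genes tested, 4094 passed from 5 to 9 dpf, 7820 had an unadjusted p under 0.05, and 1262 passed and also changed at least 2-fold. The count was 3053 higher and 1041 lower, 74.6% higher. The split depended on scaling. After quantile scaling 5118 genes passed with 53.2% higher, after cyclic loess 5221 with 55.1% higher, and after TMM 4591 with 67.3% higher. Without 9dpf_2 the count was 1820, and without 9dpf_3 it was 2306. Of the 278 calls of members of the gene lists, 140 held in every alternative and left-out library, and the genes named for the lists are taken from these 140 unless a value says otherwise. Members that the rule picks but whose calls were lost in some setting are thus not all named.

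**Figure D1:**
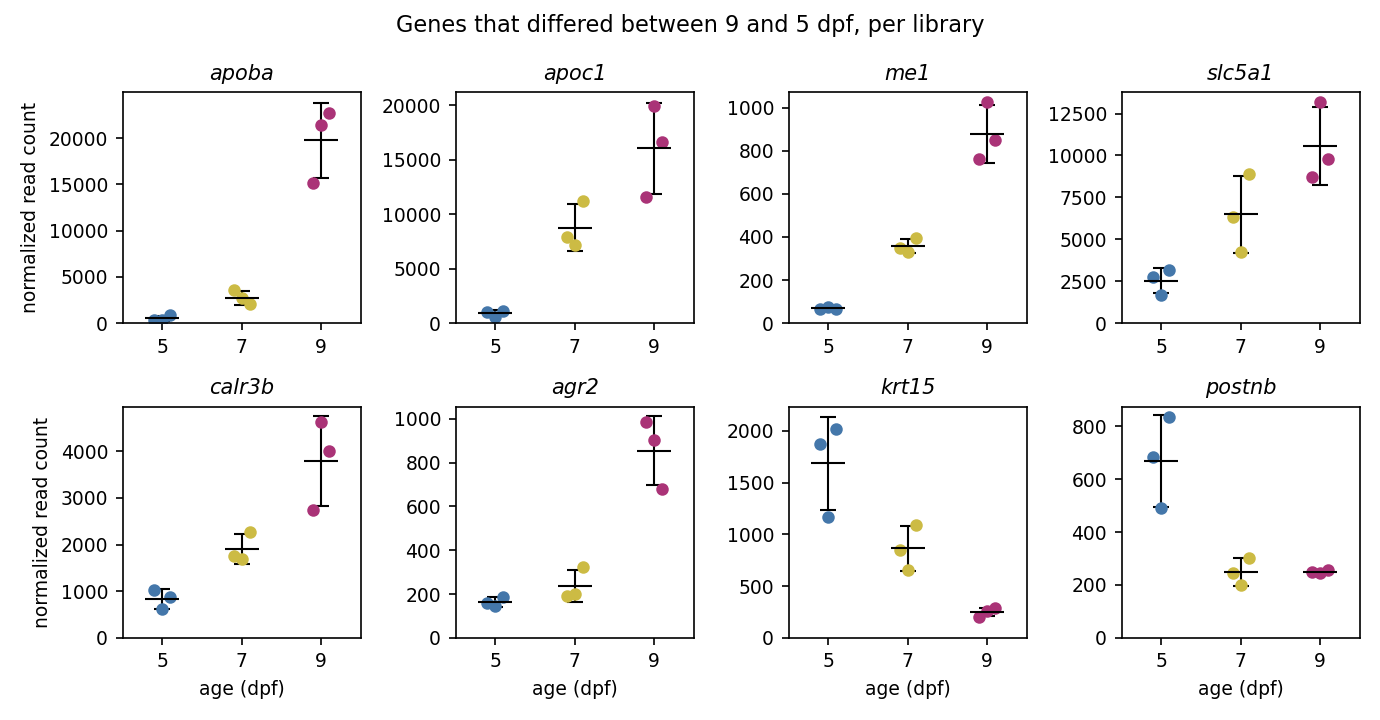
Normalized read counts (vertical axis) of 8 genes against age in dpf, with a point for each library and a bar at the mean with its SD over 3 libraries per age. apoba, apoc1, me1, slc5a1, calr3b and agr2 were higher in all 3 libraries of 9 dpf than in any of 5 dpf, and krt15 and postnb were lower, apoba going from 524 to 19763 and krt15 from 1687 to 251.

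The lists of the absorbing epithelium had more members higher than lower at 9 against 5 dpf, with a balance that depended on scaling. Of 41 genes of lipid absorption and lipoproteins, 27 rose and 1 fell (29 and 2 adjusted over the list alone; camera adjusted p = 1.19e-11, and adjusted p = 0.592 with an estimated correlation). Without 9dpf_2 the risers were 17. After quantile scaling 25 were higher and 6 lower, and after cyclic loess 26 and 6, the median going from log2 0.95 to 0.46 and 0.49. Besides apoba and apoc1 they included apoeb (log2 2.97), the sterol exporter abcg5 (2.44), the lipoprotein receptor scarb1 (2.38) and mtp (1.25), the transfer protein that loads lipid onto apolipoprotein B. apoa1b, the member that fell, did so by log2 1.47 (adjusted p = 0.0356, and 0.00417 to 0.0957 over 19 settings). Its adjusted p was 0.0646 with the replicate block, 0.0806 without 5dpf_1, 0.0553 without 5dpf_3, 0.0957 without 9dpf_1 and 0.0932 without 9dpf_3. Of 44 genes of brush border digestion and nutrient transport, 17 rose and 1, slc9a3.2, fell (21 and 1 adjusted over the list alone; camera adjusted p = 7.93e-05, and adjusted p = 0.679 with an estimated correlation). The risers were 8 without 9dpf_2 and 11 without 5dpf_2 or 9dpf_3. Quantile scaling and cyclic loess each gave 16 higher and 6 lower, with the median going from log2 0.61 to 0.10 and 0.11. slc5a1, the sodium and glucose cotransporter, rose 4.23-fold from 2538 ± 748 to 10561 ± 2349, the chitinase chia.1 rose 4.30-fold, and the alkaline phosphatase alpi.2 and the meprin mep1a.1 rose by log2 1.29 and 1.65.

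Of 29 genes of lysosome-rich enterocytes, the cells that take up whole proteins, 10 rose from 5 to 9 dpf and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.000256, and adjusted p = 0.679 with an estimated correlation). The risers were 6 without 5dpf_2, 9dpf_2 or 9dpf_3. The balance depended on scaling, with 7 higher and 5 lower after quantile scaling, 7 and 4 after cyclic loess, and a median of log2 0.67 that went to 0.11 and 0.15. The cathepsin ctsla rose by log2 1.59 and the lysosomal channel mcoln1a by 1.32. The glucosidase gaa fell by log2 0.71 (adjusted p = 0.0290, and 0.0193 to 0.136 over 19 settings), and its adjusted p was 0.107 without 5dpf_2, 0.0672 without 5dpf_3, 0.136 without 9dpf_2 and 0.0784 without 9dpf_3. Of 31 genes of bile acid and xenobiotic handling, 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000946, and adjusted p = 0.673 with an estimated correlation), the risers being 5 without 5dpf_1 and 4 without 9dpf_2. For these, quantile scaling gave 6 higher and 3 lower and cyclic loess 6 and 2, and the median of log2 0.44 went to 0.09 and 0.12. nr0b2a rose most, and the cytochrome cyp2k18 rose 6.60-fold from 267 ± 130 to 1667 ± 327. The sulfotransferase sult2st1 fell by log2 0.77 (adjusted p = 0.0106, range 0.00554 to 0.0720), with 0.0720 without 9dpf_3.

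The secretory and regulatory lists were not called by camera from 5 to 9 dpf. Of 18 goblet cell genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.648), the risers being 1 without 9dpf_2. agr2 (ENSDARG00000070480), a disulfide isomerase needed for mucin secretion, rose 5.14-fold from 164 ± 21.5 to 855 ± 157 (adjusted p = 2.37e-07). galnt7, an enzyme of mucin glycosylation, rose by log2 0.98 (adjusted p = 0.00756, range 0.000317 to 0.0551), with 0.0551 without 9dpf_2. The protease capn9 fell by log2 0.69 (adjusted p = 0.0176, range 0.00250 to 0.147), with 0.0567 without 5dpf_1 and 0.147 without 9dpf_2. Of 36 enteroendocrine genes 1 rose (0 adjusted over the list alone; camera adjusted p = 0.0692). It was mlnl, a motilin-like hormone gene, by log2 0.92 (adjusted p = 0.0268, range 0.00395 to 0.133), with 0.0984 without 5dpf_2, 0.133 without 9dpf_2 and 0.0581 without 9dpf_3. Of 54 intestinal transcription factor and Notch genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.314). The risers were 2 without 5dpf_1 or 9dpf_2 and 3 without 5dpf_2 or 9dpf_3. After quantile scaling and after cyclic loess the balance was reversed, with 2 higher and 15 lower in each. CABZ01057488.2, which is hnf4b in the reference, rose 2.31-fold, and klf4 fell 5.01-fold from 633 ± 308 to 114 ± 20.4. The intestinal marker cldn15la was at 14002 ± 3925 and 17166 ± 3015 (log2 0.32, adjusted p = 0.503). After quantile scaling its sign turned, to log2 -0.36 with adjusted p = 0.00850 in a range of 0.00850 to 0.919.

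Chaperones of the endoplasmic reticulum, which fold secreted proteins, had the largest median change of the 31 lists from 5 to 9 dpf, log2 1.11, or 0.72 after quantile scaling and 0.69 after cyclic loess. Of 40 genes 31 rose and 0 fell (33 and 0 adjusted over the list alone; camera adjusted p = 5.31e-19, and adjusted p = 0.592 with an estimated correlation). calr3b rose 4.53-fold from 837 ± 213 to 3792 ± 958 and dnajb11 rose 4.31-fold from 332 ± 62.3 to 1435 ± 267. Of 56 genes of fasting and fatty acid oxidation, 26 rose and 1 fell (32 and 3 adjusted over the list alone; camera adjusted p = 7.31e-07, and adjusted p = 0.679 with an estimated correlation). The risers were 10 without 9dpf_2, 15 without 9dpf_3, 16 without 5dpf_2 and 17 without 5dpf_1. After quantile scaling 21 were higher and 9 lower, and after cyclic loess 19 and 9, with the median going from log2 0.58 to 0.22 and 0.23. hadhaa, of the mitochondrial trifunctional protein, rose 3.88-fold, the uncoupling protein gene ucp3 rose 3.82-fold, and cpt1ab, which admits fatty acids to mitochondria, rose by log2 1.62. Of 46 genes of cholesterol and fatty acid synthesis, 11 rose and 3 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.191). Its median of log2 0.06 turned to -0.16 after quantile scaling and to -0.14 after cyclic loess, with 9 and 10 higher and 12 lower in each, and the risers were 5 without 9dpf_2 and 6 without 5dpf_2 or 9dpf_3. me1 rose most, the elongase elovl6 rose 4.09-fold and the desaturase fads2 by log2 1.99, while sqlea, an enzyme of cholesterol synthesis, fell by log2 0.96 and mid1ip1l fell by 1.07.

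The lists of smooth muscle, liver, skeletal muscle, enteric neurons and transcription factors of other organs had more members lower than higher at 9 against 5 dpf. Of 44 smooth muscle and mesenchyme genes 13 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.97e-08, and adjusted p = 0.592 with an estimated correlation), with 7 without 5dpf_1, 5dpf_3 or 9dpf_3. The fallers were 27 after quantile scaling and after cyclic loess, the median going from log2 -0.41 to -0.64 and -0.62. postnb, a matrix protein, fell 2.61-fold from 669 ± 173 to 250 ± 6.09, the proteoglycan lum fell 3.01-fold, and the collagen gene col1a1b fell by log2 1.15. Of 54 liver genes 8 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 6.57e-08, and adjusted p = 0.649 with an estimated correlation), the fallers being 5 without 9dpf_2 or 9dpf_3. The urate oxidase uox fell 3.12-fold, the complement gene c9 fell 2.38-fold, lect2l rose 4.34-fold and the coagulation factor f5 rose 1.95-fold. Of 32 skeletal muscle genes 8 fell and 0 rose (17 and 0 adjusted over the list alone; camera adjusted p = 2.38e-07, and adjusted p = 0.592 with an estimated correlation). The fallers were 13 after TMM, 2 without 9dpf_2, 3 without 5dpf_1 and 5 without 9dpf_1 or 9dpf_3. The fast myosin myhz2 fell 1.99-fold, from 126 ± 17.7 to 62.5 ± 1.01. Of 36 enteric neuron and glia genes 4 fell and 0 rose (0 adjusted over the list alone; camera adjusted p = 7.22e-05, and adjusted p = 0.592 with an estimated correlation), with 1 without 5dpf_1 and 0 without 9dpf_2 or 9dpf_3. The fallers were 2 after quantile scaling and after cyclic loess. The glial gene gfap was 1.70-fold lower (adjusted p = 0.0462, range 0.0302 to 0.162), with 0.120 without 5dpf_2, 0.137 without 5dpf_3, 0.162 without 9dpf_2 and 0.149 without 9dpf_3. Its call was also lost after quantile scaling (0.0779), after cyclic loess (0.0908) and with no filter (0.0580). Of 146 developmental transcription factors of other organs 6 fell and 3 rose (0 and 3 adjusted over the list alone; camera adjusted p = 2.91e-05, and adjusted p = 0.679 with an estimated correlation). The fallers were 3 without 5dpf_1, 2 without 5dpf_2, 5dpf_3 or 9dpf_3, and 0 without 9dpf_2. After quantile scaling 4 rose and 2 fell, and after cyclic loess 5 and 2. mnx2b, of motor neurons and endoderm, rose 3.71-fold, and ascl1b, also active in enteroendocrine precursors, rose 3.07-fold. The fallers picked by the rule, msx1a and sox11a, lost their calls in several settings. Without 9dpf_2 they were at log2 -0.78 (adjusted p = 0.147) and -0.97 (0.131), and sox11a had 0.0586 after quantile scaling.

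Further lists of other cells gave few calls from 5 to 9 dpf. Of 26 epidermis and pigment cell genes 2 fell and 1 rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.0445, and adjusted p = 0.649 with an estimated correlation), the keratin gene krt91 falling 3.39-fold and dct rising 1.69-fold, with 5 lower after quantile scaling and after cyclic loess. Of 22 genes of kidney, swim bladder and heart 2 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.660). The risers, slc13a1 and the cadherin cdh17 (2.45-fold), are also known in the intestine, and the heart myosin myh6 fell by log2 0.75 (adjusted p = 0.00813, range 0.000640 to 0.0824), with 0.0824 without 9dpf_2. Of 17 erythrocyte genes 2 rose and 1 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.251), the heme synthesis genes urod and fech rising 2.26-fold and 2.24-fold. Of 30 exocrine pancreas genes 1, cuzd1.1, rose, by 3.09-fold (1 adjusted over the list alone; camera adjusted p = 0.314). Of 15 pancreatic islet genes 0 passed in limma (0 adjusted over the list alone; camera adjusted p = 0.0686), with gcga, which encodes glucagon, at 156 ± 13.6 and 160 ± 15.9.

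Immune lists were not called by camera from 5 to 9 dpf. Of 49 myeloid leukocyte genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.461). lect2l, which is in this list as well as in the liver list, rose, and ncf4, of the phagocyte oxidase, fell by log2 0.95. mpx also rose and cebpb fell, but mpx had adjusted p = 0.125 with the replicate block (log2 1.58) and cebpb 0.0622 without 9dpf_2 (log2 -0.83). Of 49 lymphoid cell genes 0 passed in limma (0 adjusted over the list alone; camera adjusted p = 0.0501), with tox at 109 ± 7.87 and 98.3 ± 9.28. Of 69 genes of intestinal inflammation and antimicrobial defence 7 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.825), the risers being 4 without 5dpf_1. stat3, which passes on cytokine signals, rose 2.26-fold from 669 ± 201 to 1472 ± 119, and the complement gene c3a.1 fell from 570 ± 251 to 233 ± 7.57.

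Cell cycle, stress, clock and housekeeping lists complete the comparison of 9 with 5 dpf. Of 69 cell proliferation genes 12 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.443), with 1 without 9dpf_2 and 6 without 5dpf_2. After quantile scaling 8 were higher and 5 lower, and after cyclic loess 10 and 4. The tubulin tubb4b rose by log2 1.39, and pcna, the sliding clamp of replication, by 0.94 (adjusted p = 0.0159, range 0.00450 to 0.0801), with 0.0801 without 9dpf_2 and 0.0686 without 5dpf_2. Of 40 immediate early and heat shock genes 11 fell and 5 rose (12 and 5 adjusted over the list alone; camera adjusted p = 0.0305, and adjusted p = 0.679 with an estimated correlation). The fallers were 5 without 5dpf_1, 6 without 9dpf_1 or 9dpf_2, and 7 without 5dpf_3 or 9dpf_3, and the risers 3 without 5dpf_2 or 9dpf_2. fosb fell 2.67-fold and klf2a 2.56-fold, while the chaperone genes hspa4a and dnajb1b rose 3.09-fold and 3.01-fold. Of 38 circadian clock genes 10 fell and 6 rose (10 and 6 adjusted over the list alone; camera adjusted p = 0.407, direction down), the risers being 3 without 9dpf_2 or 9dpf_3. The median of log2 0.06 turned to -0.30 after quantile scaling and -0.28 after cyclic loess, with 15 and 14 lower and 5 and 4 higher. nr1d1, a repressor of the clock, fell 3.68-fold from 700 ± 148 to 191 ± 54.0, ciartb fell 2.88-fold, and cry1bb and arntl1b rose 2.32-fold and 2.02-fold. Of 13 mitochondrially encoded genes 0 passed in limma (0 adjusted over the list alone), and camera did not call the list. mt-co1 was at 109060 ± 6646 and 140840 ± 21763, and the median of log2 0.46 turned to -0.19 and -0.11 after quantile scaling and cyclic loess. Of 88 cytosolic ribosomal protein genes 3 rose, RPS27L among them (3 adjusted over the list alone; camera adjusted p = 0.00223, and adjusted p = 0.730 with an estimated correlation). Here the median of log2 0.33 turned to -0.26 after quantile scaling and -0.23 after cyclic loess, with 50 and 40 members called lower there.

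The chromatin lists bear on the enzymes behind both marks. ezh2 (ENSDARG00000010571), the methyltransferase of H3K27, rose 1.66-fold from 359 ± 33.6 at 5 dpf to 599 ± 69.2 at 9 dpf (log2 0.73, SE 0.19, adjusted p = 0.0107, range 0.00120 to 0.0682), and without 9dpf_2 its adjusted p was 0.0682. kdm6bb (ENSDARG00000056929), a demethylase of H3K27, fell 1.69-fold from 356 ± 48.4 to 210 ± 19.9 (log2 -0.76, SE 0.18, adjusted p = 0.00512). Its paralogue kdm6ba was at 1316 ± 245 and 1226 ± 162 (log2 -0.09, adjusted p = 0.805), and it passed after quantile scaling and after cyclic loess, both lower with adjusted p = 0.000680 in a range of 0.000680 to 0.996. suz12a (log2 0.36, adjusted p = 0.214), suz12b (0.38, adjusted p = 0.176) and eed (0.11, adjusted p = 0.739), the partners of ezh2, did not pass. Of the 43 Polycomb group and H3K27 demethylase genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.461), the risers being 0 without 9dpf_2 and 2 without 5dpf_2 or 9dpf_3. After quantile scaling 3 were higher and 7 lower, and after cyclic loess 4 and 7. Of 36 genes of H3K4 methyltransferase complexes and demethylases 4 rose (3 adjusted over the list alone; camera adjusted p = 0.0692), with 2 without 9dpf_2. kdm1a rose by log2 0.92 and hcfc1a by 0.86, and the median of log2 0.16 turned to -0.12 after quantile scaling and after cyclic loess, with 3 higher and 6 lower in each. Of 49 Hox genes 5 rose (5 adjusted over the list alone; camera adjusted p = 0.282), hoxa9a by log2 1.14 and hoxd4a by 0.98, and the median of log2 0.05 turned to -0.00 after TMM. hoxb13a, of the posterior gut, was at 213 ± 12.6 and 218 ± 50.4 (log2 0.01, adjusted p = 0.980). Over the 31 lists camera called 14 from 5 to 9 dpf, 7 up and 7 down, and 0 with an estimated correlation.

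**Figure D2:**
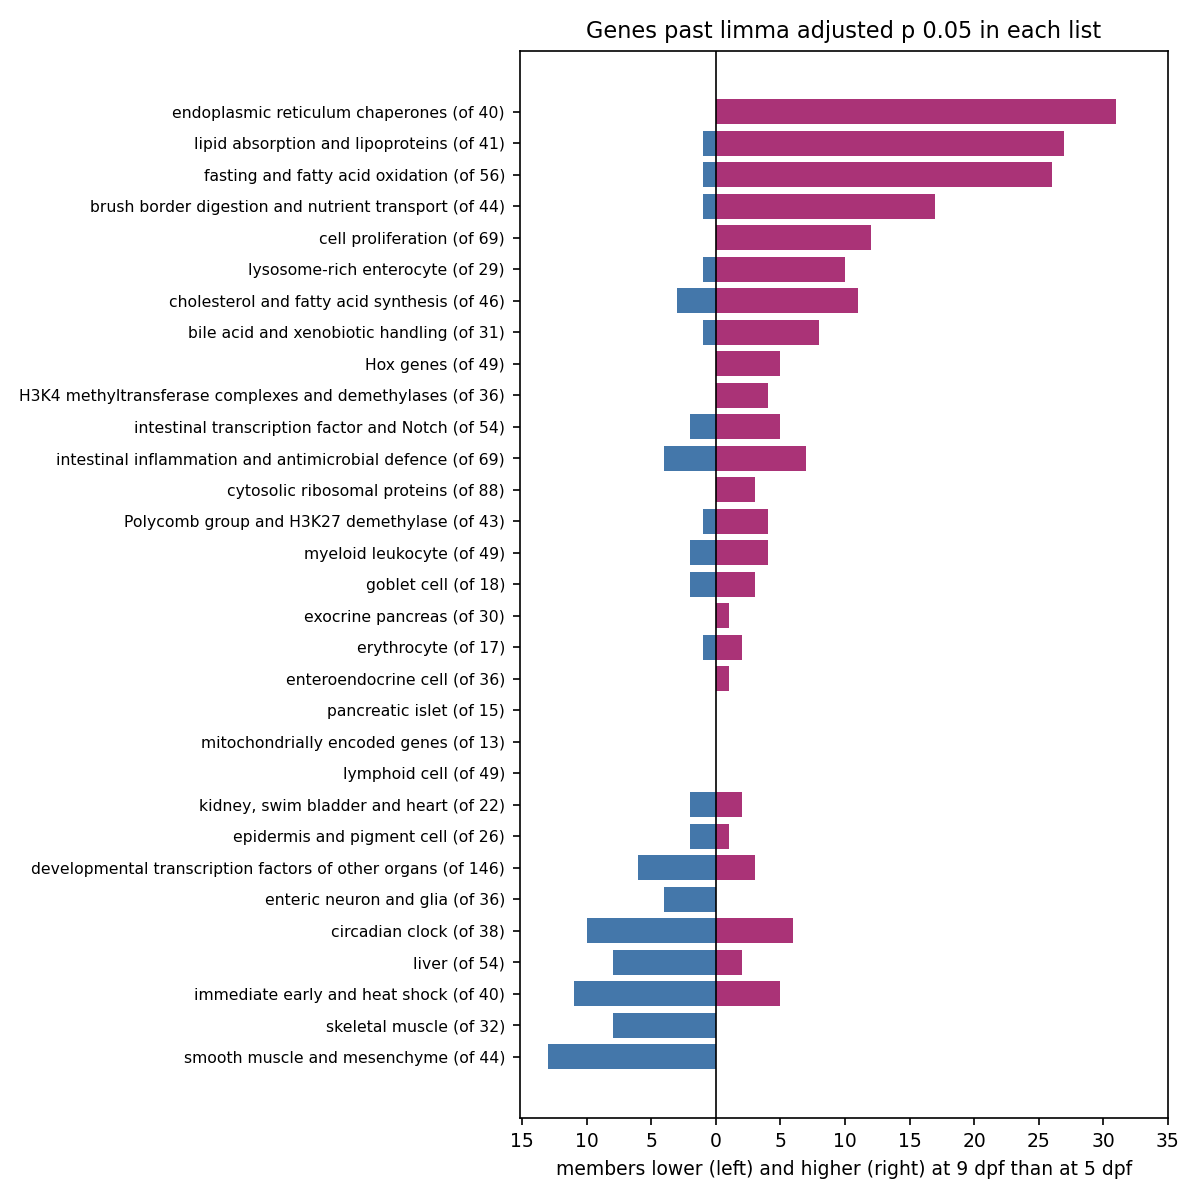
Number of members (horizontal axis, genes) of each of the 31 lists that passed limma lower (left, blue) or higher (right, purple) at 9 dpf than at 5 dpf, with the number tested in brackets. Endoplasmic reticulum chaperones had 31 higher and 0 lower, lipid absorption and lipoproteins 27 and 1, and smooth muscle and mesenchyme 0 and 13.

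The comparison of 7 with 5 dpf covers the first step. mt2 rose 27.8-fold, from 39.2 ± 14.9 to 1141 ± 465 (log2 4.80, SE 0.35, adjusted p = 1.70e-05), nr0b2a (ENSDARG00000044685) rose 14.3-fold, from 359 ± 148 to 5236 ± 2686 (log2 3.83, SE 0.46, adjusted p = 0.000924), and apoc1 rose 9.45-fold to 8771 ± 2173 (log2 3.24, SE 0.30, adjusted p = 1.18e-06). nr1d1 (ENSDARG00000033160) fell 3.65-fold to 188 ± 0.987 (adjusted p = 1.70e-05), and cyp7a1, the enzyme that limits bile acid synthesis, fell 3.56-fold from 2518 ± 763 to 715 ± 275 (adjusted p = 0.000697). mki67 (ENSDARG00000091150), a marker of dividing cells, fell 2.47-fold from 358 ± 38.4 to 145 ± 21.9 (adjusted p = 0.000191).

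The other rises of the first 10 were those of HERC5 (7.14-fold), apoa1a (6.59-fold), cyp24a1 (6.55-fold), the enzyme that breaks down active vitamin D, ypel3 (6.30-fold), afp4 (6.18-fold), slc13a1 (5.62-fold) and apoba (5.61-fold). The other falls were those of jdp2b (4.38-fold), sfrp5 (4.32-fold), the kinase gene sik1 (3.57-fold), the channel subunit kcne4 (3.41-fold) and the clock gene ciartb (3.29-fold), and of fosab, midn and hist2h3c. With 5dpf_2, 7dpf_2 and 9dpf_1, the libraries of most positive tilt (weak genes up) at each age, all left out, the calls of cyp24a1 (adjusted p = 0.0526, range from 7.94e-05), afp4 (0.226, range from 1.32e-08) and jdp2b (0.0828, range from 2.51e-08) were lost, at log2 2.60, 2.32 and -2.02 against 2.71, 2.63 and -2.13 with all libraries. For fosab, 4.07-fold lower (adjusted p = 0.0273, range 3.71e-08 to 0.281), the value was 0.144 without 5dpf_2, 0.103 without 7dpf_1, 0.0623 without 7dpf_2 and 0.0952 without 7dpf_3. For midn, 3.51-fold lower (adjusted p = 0.0464, range 4.66e-12 to 0.146), it was 0.0974 without 5dpf_1, 0.113 without 5dpf_3, 0.146 without 7dpf_1 and 0.120 without 7dpf_2. For the histone gene hist2h3c, 3.45-fold lower (adjusted p = 0.0140, range 2.68e-07 to 0.102), it was 0.0506 without 5dpf_1 and 0.102 without 7dpf_1.

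Of the genes tested 985 passed from 5 to 7 dpf, 638 higher and 347 lower (64.8% higher), 4091 had an unadjusted p under 0.05, and 462 also changed at least 2-fold. After quantile scaling 2275 passed with 54.0% higher, and after cyclic loess 2089 with 52.3% higher. The balance turned without 5dpf_2, to 405 higher and 458 lower (46.9% higher), and without 7dpf_3, to 266 and 339 (44.0% higher). The count was 315 without 7dpf_1, 479 without 5dpf_1, 605 without 7dpf_3, 1528 without 7dpf_2, and 2121 with 5dpf_2, 7dpf_2 and 9dpf_1 all left out. Of 133 calls of list members 48 held in every alternative, those of mki67, apoc1, fdps and nr1d1 among them.

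By list, 15 of 56 genes of fasting and fatty acid oxidation rose from 5 to 7 dpf and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 1.26e-12, and adjusted p = 0.629 with an estimated correlation). ucp3 rose by log2 2.24 and sesn1, a stress sensor that restrains growth signals, by 1.86, and the risers were 6 without 7dpf_1, 8 without 7dpf_3, and 9 without 5dpf_1 or 5dpf_2. After quantile scaling 22 were higher and 3 lower, and after cyclic loess 19 and 3, with the median going from log2 0.48 to 0.24 and 0.20. Lipid absorption and lipoproteins had 13 of 41 higher and 0 lower (17 and 1 adjusted over the list alone; camera adjusted p = 4.48e-11, and adjusted p = 0.629 with an estimated correlation), apoeb by log2 2.16, and the median of log2 0.59 went to 0.21 after quantile scaling and 0.16 after cyclic loess. Endoplasmic reticulum chaperones had 11 of 40 higher and 0 lower (19 and 0 adjusted over the list alone; camera adjusted p = 1.30e-08, and adjusted p = 0.629 with an estimated correlation), a count of 0 without 7dpf_1, 2 without 7dpf_3, 5 without 5dpf_2 and 6 without 5dpf_1. Cell proliferation had 16 of 69 lower and 1 higher (23 and 7 adjusted over the list alone; camera adjusted p = 1.70e-05, and adjusted p = 0.629 with an estimated correlation), with 10 lower without 7dpf_1. cdk1, the kinase that drives mitosis, fell by log2 1.65, ube2c fell by 1.32 and top2a fell by 1.04. Cholesterol and fatty acid synthesis had 9 of 46 lower and 4 higher (15 and 5 adjusted over the list alone; camera adjusted p = 0.0267, and adjusted p = 0.629 with an estimated correlation). The fallers were 2 without 7dpf_1 and 5 without 5dpf_1 or 5dpf_3, and the risers 2 without 5dpf_2, 7dpf_1 or 7dpf_3. After quantile scaling the fallers were 19 and after cyclic loess 20, with 4 higher in each. fdps, of the mevalonate pathway, fell by log2 1.45 and sqlea fell by 1.65, while me1 rose by 2.34.

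Immediate early and heat shock genes had 10 of 40 lower and 1 higher from 5 to 7 dpf (13 and 1 adjusted over the list alone; camera adjusted p = 5.26e-06, and adjusted p = 0.629 with an estimated correlation), with 4 lower without 7dpf_1 and 5 without 5dpf_1. nr4a1 fell by log2 1.56 and klf2a fell by 0.92. Smooth muscle and mesenchyme had 7 of 44 lower and 0 higher (12 and 0 adjusted over the list alone; camera adjusted p = 2.44e-09, and adjusted p = 0.629 with an estimated correlation), with postnb down by log2 1.41. The fallers were 1 without 5dpf_1 or 7dpf_1, 2 without 5dpf_3 and 12 without 5dpf_2, and 11 after TMM, 20 after quantile scaling and 21 after cyclic loess. The circadian clock list had 7 of 38 lower and 3 higher (7 and 6 adjusted over the list alone; camera adjusted p = 0.393), and its median of log2 0.00 turned to -0.05 under TMM and -0.13 under quantile scaling and cyclic loess. The fallers were 4 without 5dpf_3 or 7dpf_1, and the risers 0 without 7dpf_1 or 7dpf_3, 1 without 5dpf_1 and 5 without 7dpf_2. Quantile scaling gave 12 lower and 5 higher, and cyclic loess 13 and 5. camera also called brush border (up, adjusted p = 0.00276), lysosome-rich enterocyte (up, 0.000395), bile acid and xenobiotic handling (up, 0.0137), exocrine pancreas (up, 1.65e-06), ribosomal proteins (up, 5.08e-10) and Hox genes (up, 0.0129). Of these, some medians shrank after quantile scaling and cyclic loess, from log2 0.47 to 0.02 and 0.03 for brush border, from 0.42 to 0.14 and 0.10 for lysosome-rich enterocytes, from 0.31 to 0.13 and 0.11 for bile acid and xenobiotic handling, and from 0.51 to 0.03 and 0.06 for ribosomal proteins. It called the H3K4 list up (0.0267), its median turning under quantile scaling and cyclic loess, and liver (0.00852), lymphoid cells (0.0132), transcription factors of other organs (0.0276) and erythrocytes (0.0276) down. With an estimated correlation these had adjusted p = 0.629, or 0.677 for the transcription factors. That makes 18 of 31 lists, 10 up and 8 down, and 0 with an estimated correlation.

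The comparison of 9 with 7 dpf covers the second step. LCT (1 of many) (ENSDARG00000092404) rose 8.40-fold, from 874 ± 316 to 7288 ± 2435 (log2 3.07, SE 0.28, adjusted p = 1.85e-06), apoba rose 7.22-fold, from 2763 ± 758 to 19763 ± 4049 (log2 2.85, SE 0.32, adjusted p = 3.54e-05), and agr2 rose 3.64-fold, from 238 ± 73.1 to 855 ± 157 (log2 1.87, SE 0.21, adjusted p = 4.23e-05). eevs (ENSDARG00000087873), of the pathway that makes the sunscreen compound gadusol, rose 7.87-fold, from 105 ± 41.4 to 793 ± 112 (adjusted p = 1.47e-06, range 2.52e-25 to 0.0876), and lost its call only with 5dpf_2, 7dpf_2 and 9dpf_1 all left out, where log2 was 3.03 against 2.98 with all libraries, so its fold was not smaller there. lpin1 (ENSDARG00000020239), a phosphatase of lipid synthesis, fell 3.82-fold from 3346 ± 1307 to 869 ± 326 (adjusted p = 0.00621).

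The other rises of the first 10 in the second step were those of soul5 (3.25-fold), of 3 genes named MFAP4 (1 of many), 4.17-fold to 4.68-fold, and of plac8.2 and hist2h3c. The other falls were those of krt15 (3.40-fold), miox (3.31-fold), the muscle myosin myhz1.1 (2.75-fold), the histidine degrading uroc1 (2.74-fold), cyp24a1 (5.42-fold), dio3b (3.47-fold), tat (3.11-fold), igfbp1b (2.85-fold) and diabloa (2.73-fold). For plac8.2, 3.40-fold higher (adjusted p = 0.0448, range 9.89e-06 to 0.473), the value was 0.0968 without 7dpf_1, 0.265 without 7dpf_2, 0.0928 without 9dpf_1 and 0.0994 without 9dpf_3. For hist2h3c, 3.35-fold higher (0.0294, range 1.19e-06 to 0.172), it was 0.172 without 7dpf_1, 0.0799 without 9dpf_1, 0.162 without 9dpf_2 and 0.0971 without 9dpf_3. For cyp24a1 (0.0193, range 0.00122 to 0.0885) it was 0.0679 without 7dpf_1 and 0.0629 without 9dpf_3. For dio3b (0.0193, range 3.12e-06 to 0.158) it was 0.0594 without 7dpf_1, 0.122 without 7dpf_2, 0.0655 without 9dpf_1 and 0.0619 without 9dpf_3. For tat (0.0399, range 0.000218 to 0.334) it was 0.125 without 7dpf_2, 0.0822 without 7dpf_3, 0.123 without 9dpf_1, 0.234 without 9dpf_2 and 0.136 without 9dpf_3. For igfbp1b (0.00729, range 4.48e-05 to 0.200) it was 0.0515 without 9dpf_3, and for diabloa (0.00821, range 2.55e-06 to 0.0607) 0.0601 without 7dpf_1 and 0.0607 without 9dpf_3.

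Of the genes tested 458 passed from 7 to 9 dpf, 365 higher and 93 lower (79.7% higher), 3788 had an unadjusted p under 0.05, and 209 also changed at least 2-fold. After quantile scaling 1552 passed with 57.4% higher, and after cyclic loess 2044 with 61.4% higher. TMM gave 762, edgeR 785, DESeq2 859, a fit of only the ages compared 843, the replicate block 790, and a fit without robust estimates 272. The count was 101 without 7dpf_1, 120 without 9dpf_3, 138 without 9dpf_2, 225 without 7dpf_2, 963 without 7dpf_3, and 1231 with 5dpf_2, 7dpf_2 and 9dpf_1 all left out. Of 52 calls of list members 16 held in every alternative, those of apoba, agr2, mki67, elovl6 and pdia4 among them.

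By list, 10 of 40 endoplasmic reticulum chaperones rose from 7 to 9 dpf and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 5.11e-15, and adjusted p = 0.543 with an estimated correlation). pdia4 rose by log2 1.37 and manf by 1.46, and the count was 5 without 7dpf_1 or 9dpf_2, 6 without 9dpf_3, 18 after quantile scaling and 20 after cyclic loess. Cell proliferation had 5 of 69 higher and 0 lower (12 and 0 adjusted over the list alone; camera adjusted p = 2.14e-10, and adjusted p = 0.543 with an estimated correlation), mki67 by log2 1.02. The count was 1 without 7dpf_1, 2 without 9dpf_2 or 9dpf_3, 11 without 7dpf_3, 10 after quantile scaling and 14 after cyclic loess. Cholesterol and fatty acid synthesis had 6 of 46 higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 3.04e-07, and adjusted p = 0.543 with an estimated correlation), with elovl6 up by log2 1.63 and fdps by 1.24. The count was 3 without 7dpf_1, 9dpf_2 or 9dpf_3, 11 without 9dpf_1, and 12 after cyclic loess. Skeletal muscle had 5 of 32 lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 4.18e-08, and adjusted p = 0.543 with an estimated correlation), myhz2 by log2 -1.33, with 3 without 9dpf_2 or 9dpf_3. For mitochondrially encoded genes 0 of 13 passed in limma over all genes and 6 were higher adjusted over the list alone (camera adjusted p = 4.94e-05, and adjusted p = 0.543 with an estimated correlation), while 2 passed after quantile scaling and 4 after cyclic loess. Fasting and fatty acid oxidation had 5 of 56 lower and 1 higher (6 and 3 adjusted over the list alone; camera adjusted p = 0.798), fbp1a by log2 -1.09. The fallers were 2 without 7dpf_1 or 9dpf_1 and 3 without 9dpf_3, and the median of log2 0.04 turned to -0.05 and -0.04 after quantile scaling and cyclic loess, with 13 lower in each and 5 and 7 higher. Immediate early and heat shock genes had 5 of 40 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0971), hspa4a by log2 1.18, the risers being 2 without 7dpf_1, 9dpf_2 or 9dpf_3 and 3 without 7dpf_3 or 9dpf_1, and the balance 3 and 3 after quantile scaling and 4 and 4 after cyclic loess. Lipid absorption and lipoproteins had 2 of 41 higher and 1 lower, the cholesterol exporter abca1a by log2 -1.28 (4 and 1 adjusted over the list alone; camera adjusted p = 1.76e-05, and adjusted p = 0.590 with an estimated correlation). Here 14 were higher after quantile scaling and 17 after cyclic loess, with 1 lower in each. camera also called brush border up (0.0215; 0.760 with an estimated correlation). It called down liver (3.30e-06; 0.564), enteroendocrine cells (0.000187; 0.543), exocrine pancreas (0.000187; 0.605), enteric neuron and glia (0.000413; 0.543), transcription factors of other organs (0.000327; 0.723), intestinal transcription factors and Notch (0.0215; 0.605) and ribosomal proteins (0.0247; 0.853). Of the ribosomal proteins 0 passed in limma, while 41 were lower after quantile scaling and 50 after cyclic loess. That makes 14 of 31 lists, 6 up and 8 down, and 0 with an estimated correlation.

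Whether the steps differed was tested by subtracting the first from the second. mki67 went from 358 ± 38.4 to 145 ± 21.9 and back to 294 ± 34.6 (difference of steps log2 2.32, adjusted p = 0.000560), and fdps (ENSDARG00000040890) from 610 ± 67.3 to 225 ± 43.6 and 532 ± 83.3 (2.69, adjusted p = 0.000438). cdk1 (ENSDARG00000087554) went from 70.8 ± 8.06 to 23.4 ± 10.1 and 54.2 ± 8.99 (2.91, adjusted p = 0.00320, range 3.67e-05 to 0.0524), with 0.0524 without 7dpf_1. In the other direction sesn1 (ENSDARG00000020693) went from 916 ± 74.4 to 3345 ± 424 and 1565 ± 429 (-2.99, adjusted p = 0.000988), and abca1a (ENSDARG00000074635) from 708 ± 139 to 1802 ± 483 and 728 ± 104 (-2.62, adjusted p = 0.00197). cyp24a1 (ENSDARG00000103277) went from 974 ± 392 to 6446 ± 3183 and 1206 ± 649 (-5.15, adjusted p = 0.00988, range 5.53e-05 to 0.0840), lost only with 5dpf_2, 7dpf_2 and 9dpf_1 all left out. egr1 (ENSDARG00000037421), an immediate early gene, went from 982 ± 327 to 357 ± 116 and 719 ± 194 (2.47, adjusted p = 0.00786, range 5.22e-05 to 0.348), with 0.0757 after quantile scaling and 0.0732 after cyclic loess.

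**Figure D3:**
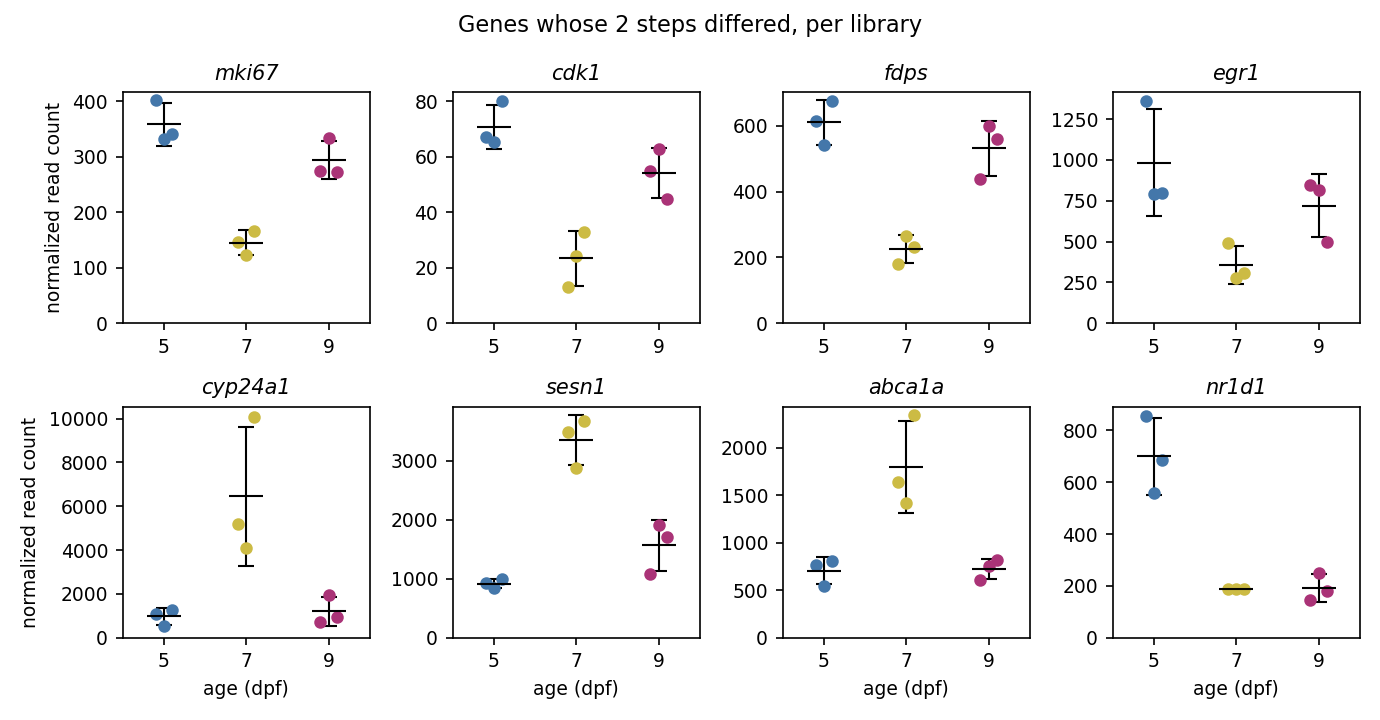
Normalized read counts (vertical axis) of 8 genes whose steps differed, against age in dpf, with a point for each library and a bar at the mean with its SD over 3 libraries per age. mki67, cdk1, fdps and egr1 were lowest at 7 dpf (mki67 358, 145 and 294), cyp24a1, sesn1 and abca1a were highest there (sesn1 916, 3345 and 1565), and nr1d1 fell to 188 at 7 dpf and stayed at 191.

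The steps differed for 244 genes, 156 with a higher and 88 with a lower second step (63.9% higher), and 2124 had an unadjusted p under 0.05. The balance turned without 7dpf_2, to 103 higher and 149 lower (40.9% higher), and was 227 and 33 without 7dpf_3 (87.3% higher). The count was 54 without 7dpf_1, 158 without 5dpf_1, 437 without 5dpf_2, and 697 with 5dpf_2, 7dpf_2 and 9dpf_1 all left out. Quantile scaling gave 802, cyclic loess 850, the replicate block 410 and DESeq2 382. Cell proliferation had 11 of 69 with a higher second step and 0 with a lower one (21 and 0 adjusted over the list alone; camera adjusted p = 4.94e-13, and adjusted p = 0.442 with an estimated correlation), with 4 without 7dpf_1. In cholesterol and fatty acid synthesis 6 of 46 were higher and 0 lower (15 and 3 adjusted over the list alone; camera adjusted p = 9.96e-07, and adjusted p = 0.442 with an estimated correlation), with 1 without 7dpf_1 and 10 without 5dpf_2, and 14 after quantile scaling and 16 after cyclic loess, with 2 lower in each. Immediate early and heat shock genes had 3 of 40 higher and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 1.62e-06, and adjusted p = 0.442 with an estimated correlation), with 1 without 7dpf_1 and 6 without 5dpf_2, and 7 after quantile scaling and after cyclic loess. In fasting and fatty acid oxidation 7 of 56 were lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 3.56e-08, and adjusted p = 0.650 with an estimated correlation), with 2 without 7dpf_1 or 7dpf_3 and 13 after quantile scaling and after cyclic loess. Skeletal muscle had 4 of 32 lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.00895, and adjusted p = 0.650 with an estimated correlation), myhz1.1 by log2 -2.43, with 1 without 7dpf_2 or 7dpf_3 and 2 without 5dpf_1, 9dpf_1 or 9dpf_2. The largest list shifts without any member past the limma threshold were those of exocrine pancreas (median log2 -1.21; camera adjusted p = 1.91e-09, and adjusted p = 0.442 with an estimated correlation), mitochondrially encoded genes (median log2 0.98; camera adjusted p = 2.05e-05, and adjusted p = 0.442 with an estimated correlation) and ribosomal proteins (median log2 -0.71; camera adjusted p = 1.91e-09, and adjusted p = 0.719 with an estimated correlation). The last median was -0.33 after quantile scaling and -0.36 after cyclic loess, with 2 and 3 lower, and of the mitochondrially encoded genes 7 and 6 were higher there (median 1.24 and 1.39). camera called 14 of 31 lists, 6 up and 8 down, and 0 with an estimated correlation.

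The ChIP-seq lists ask where the marks lay at each age. H3K27me3 peaks were more numerous at 9 dpf than before. The lists held 5934 ± 325 peaks at 5 dpf, 5956 ± 48.1 at 7 dpf and 8936 ± 259 at 9 dpf (n = 2 libraries each), 50.6% more at 9 than at 5 dpf. They covered 11.4 ± 0.0626 Mb at 5 dpf, 11.4 ± 0.0297 Mb at 7 dpf, and 15132809 and 14911584 bases in the libraries of 9 dpf. H3K4me3 peaks rose less in number, from 16885 ± 86.3 to 17680 ± 33.2 and 18696 ± 146, 10.7% more at 9 than at 5 dpf. They covered 16.8 ± 1.93 Mb at 5 dpf, 20.2 and 19.7 Mb at 7 dpf, and 21.9 ± 0.286 Mb at 9 dpf. For each of these the libraries of 9 dpf lay above those of 5 dpf, with an exact permutation p = 0.333, two-sided, the smallest that 2 against 2 libraries allow. For H3K27me3 peaks of 7 against 5 dpf the exact permutation p = 1. The median fold enrichment by the authors for H3K4me3 was 8.50 and 8.34 at 5 dpf, 9.20 and 9.10 at 7 dpf and 11.6 or more at 9 dpf, and it lay between 3.90 and 4.29 in all H3K27me3 libraries. With only peaks above the median score counted, H3K4me3 peaks were 112% more numerous at 9 than at 5 dpf, 11464 ± 0 against 5416 ± 3362. The size of this rise is uncertain, since the libraries of 5 dpf differed widely, with median scores of 199 and 304. The input libraries gave 738, 717 and 809 peaks, which overlapped between 0.0215% and 0.974% of the peaks of a ChIP library.

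**Figure D4:**
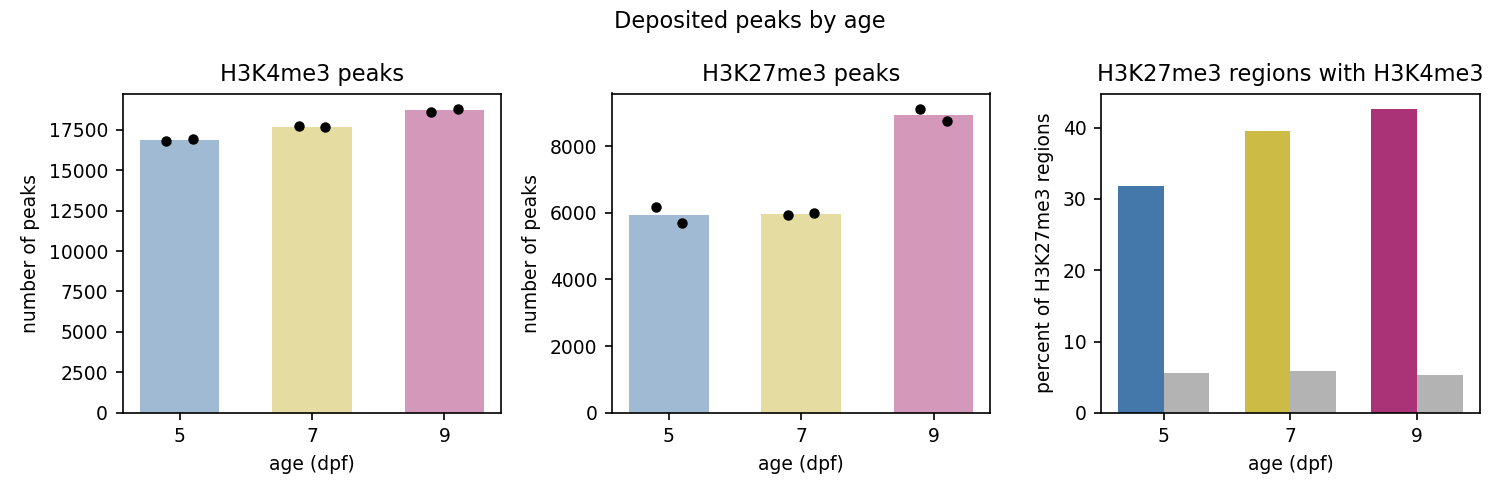
Left and middle, number of deposited H3K4me3 and H3K27me3 peaks (vertical axis) against age in dpf, with a point for each of 2 libraries and a bar at their mean; right, percent of H3K27me3 regions that overlapped an H3K4me3 region at each age (coloured) and the mean of 100 circular shifts (grey). H3K27me3 peaks went from 5934 and 5956 to 8936, and the overlap from 31.8% to 39.5% and 42.6%.

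On average libraries of the same age shared more bases than libraries of different ages. The mean Jaccard index was 0.812 within and 0.748 between ages for H3K4me3, and 0.678 and 0.607 for H3K27me3. The H3K4me3 pair of 5 dpf, at 0.766, lay below the pairs of 7 with 9 dpf, at 0.786 to 0.794. Each difference, 0.0637 and 0.0704, was the largest of the 15 ways to pair 6 libraries, a one-sided exact permutation p = 0.0667, the smallest this design allows. Merged over libraries there were 20118 H3K4me3 regions, 15400 of them in all 6 libraries, and 12236 H3K27me3 regions, 3410 of them in all 6. The longest regions in all 6 libraries were chr 13 5433577-5444517 for H3K4me3, 10941 bases, and chr 23 35938846-36025984 for H3K27me3, 87139 bases with a mean fold enrichment by the authors of 5.18. The next longest H3K27me3 regions were chr 6 33479428-33537762 (58335 bases) and chr 9 1957603-2015395 (57793 bases).

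From 5 to 9 dpf 1497 H3K27me3 regions were gained and 180 lost, a sum of 1677 against 203 in the larger of the other 2 splits of the same libraries. The gains fell in the second step, with 1379 gained and 100 lost from 7 to 9 dpf and 290 gained and 351 lost from 5 to 7 dpf, where the larger other splits gave 238 and 258. For H3K4me3 1330 regions were gained and 63 lost from 5 to 9 dpf (119 in the larger other split), 597 and 89 from 5 to 7 dpf (154), and 671 and 104 from 7 to 9 dpf (158). The gained H3K4me3 region with the highest score on a chromosome was chr 6 58575430-58577013 (score 481, fold enrichment 12.6), followed by chr 20 6164774-6165631 (score 381), and the highest lost was chr 24 12270714-12271343 (266.5, 3.76). For H3K27me3 they were chr 4 76326815-76327055 (168.5, 3.51) and, lost, chr 24 12229418-12230434 (210.5, 2.63), each n = 2 libraries. These lost regions had folds below the medians of the 5 dpf lists, 8.50 and 8.34 for H3K4me3 and 4.13 and 3.90 for H3K27me3. A further lost region was nearly the same for both marks, chr 16 15767943-15768702 for H3K4me3 (fold 1.99) and 15767937-15768705 for H3K27me3 (1.83). Whether local background at 5 dpf made such losses was not tested. The gains depended on list length. With an equal number of top-scored peaks per library, 518 H3K27me3 regions were gained and 386 lost from 5 to 9 dpf, and 423 and 291 from 7 to 9 dpf. That setting gave 466 and 223 for H3K4me3 from 5 to 9 dpf, 330 and 178 from 5 to 7 dpf, and 285 and 218 from 7 to 9 dpf. With a region counted only where a peak covered 50% of it, 1116 H3K4me3 regions were gained from 5 to 7 dpf and 2236 from 5 to 9 dpf.

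Regions with both marks in both libraries of an age became more numerous. The libraries were pools of whole intestines, so an overlap does not place both marks in the same cells. The peak lists of both marks were also longest at 9 dpf. At 5 dpf 1355 of 4263 H3K27me3 regions (31.8%) overlapped an H3K4me3 region, at 7 dpf 1677 of 4242 (39.5%) and at 9 dpf 2689 of 6307 (42.6%). Circular shifts gave means of 239, 249 and 332, and 0 of 100 shifts reached the observed number at any age. Seen from H3K4me3, 1411 of 15698, 1754 of 16830 and 2848 of 17852 regions carried H3K27me3. Of the H3K27me3 regions kept from 5 to 9 dpf 50.1% lay on H3K4me3 at 9 dpf, and of the gained ones 31.0% (464 of 1497). An overlap of 1 base is likelier for a longer region. The gained regions had a median width of 895 bases, and the longest in all 6 libraries had 87139. Lengths were not matched, so the lower share does not show that gained regions avoid H3K4me3. With a peak in any library of an age in place of both, 2035 regions at 5 dpf carried both marks.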

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

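The result least foreseen was that the 5 to 7 dpf step and the 7 to 9 dpf step differed for 244 genes in limma, and this was tested by the contrast of the steps. Most of the named genes below had a lower second step. HERC5 rose and then fell (difference of steps log2 -4.04), as did cyp24a1 (-5.15) and the myosin gene myhz1.1 (-2.43). The growth factor binding protein igfbp1b (-2.49), the myosin gene myhz2 (-1.66), fbp1a (-1.52) and uroc1 (-1.58) passed only in the second step, where they fell. Genes that rose in the first step and had a smaller second step were mt2 (-3.75), nr0b2a (-4.14), apoc1 (-2.38), slc13a1 (-1.74), ucp3 (-2.54) and ypel3 (-2.68).

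A higher second step was found for eevs (2.89), which rose only after 7 dpf, and for genes that fell before 7 dpf. Of the latter, cyp7a1 (3.17) and hist2h3c (3.53) rose from 7 to 9 dpf, sqlea (2.35) did not pass in that step, and sfrp5 (2.29), nr1d1 (1.85), ciartb (1.91), sik1 (1.78) and kcne4 (1.88) stayed near their 7 dpf level. The calls of HERC5, ypel3, ucp3, sfrp5 and myhz1.1 held in all 21 settings tried. Of 44 calls of list members in the contrast of steps, only 9 held in every setting. The hour of dissection, which bears on rhythmic genes such as nr1d1 and ciartb, was not analysed here.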

How the results depend on the processing

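Genes past the threshold from 5 to 7 dpf (985 in the result given) were 2275 after quantile scaling, 2089 after cyclic loess, 462 with a change of at least 2-fold as well, and 2121 without 5dpf_2, 7dpf_2 and 9dpf_1, the libraries of most positive tilt (weak genes up) at each age. Leaving out 1 library gave 315 (7dpf_1) to 1528 (7dpf_2). From 7 to 9 dpf (458) they were 762 after TMM, 1552 after quantile scaling, 2044 after cyclic loess, 785 in edgeR, 859 in DESeq2, 843 with only the ages compared in the fit, 272 without robust estimates, 209 with a 2-fold change, and 1231 without these 3 libraries. Leaving out 1 library gave 101 (7dpf_1) to 963 (7dpf_3). From 5 to 9 dpf (4094) the count was 1262 with a 2-fold change, and 1820 (9dpf_2) to 4561 (9dpf_1) with 1 library left out. Genes whose steps differed (244) were 802 after quantile scaling, 850 after cyclic loess, 382 in DESeq2, 697 without these 3 libraries, and 54 (7dpf_1) to 437 (5dpf_2) with 1 library left out. Cyclic loess and the fit without the 3 libraries were added after the values were seen. Where 2 libraries of an age remain, limma pools the spread of the other ages.

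With a replicate block for the library numbers the counts were 1240, 790 and 4148 for 7 against 5, 9 against 7 and 9 against 5 dpf, and 410 for the steps. Libraries of the same number in different ages had deviation correlations of -0.42 to 0.47, the highest that of 5dpf_2 with 7dpf_2, and 1 of 9 libraries correlated best with its own number. Over all pairs of ages the highest correlations, 0.455 to 0.467, joined 5dpf_2, 7dpf_2 and 9dpf_1, the libraries of most positive tilt. The correlations may thus follow the tilt and cannot exclude a pairing. The numbers are not read as a pairing, and the cause of the higher counts was not tested.

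Named genes gave 146 results for 124 genes, of which 134 passed and 95 of these held in every setting. Over all settings 2595 values kept the call, 165 lost it and 2 gained it, both for kdm6ba. In 1 case the sign turned: cldn15la from 5 to 9 dpf was at log2 0.32 and went to -0.36 after quantile scaling.

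Lists called by camera, 18, 14, 14 and 14 of 31 for 7 against 5, 9 against 7, 9 against 5 dpf and the steps, came to 0, 0, 0 and 0 with an estimated correlation, where the lowest adjusted p values were 0.629, 0.543, 0.592 and 0.442. The rotation test fry called 0, 0, 2 and 0. The other settings of the list tests stayed within 1.5 times.

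The change in H3K4me3 peak number from 5 to 9 dpf, 10.7%, was 112% for peaks above the median score, and 11.9% with peaks within 1000 bases merged. The 112% rests on a 5 dpf mean of 5416 with an SD of 3362. H3K4me3 regions gained from 5 to 7 dpf (597) were 330 with an equal number of peaks per library, 1116 where a peak covered 50% of a region, and 803 to 1169 with 1 library left out. Those lost (89) were 178 and 154 to 328. From 7 to 9 dpf the gained (671) were 285 with an equal number and 960 to 1233 with 1 left out, and the lost (104) 218 and 189 to 296. From 5 to 9 dpf the gained (1330) were 466, 2236 with 50% covered and 1604 to 2030, and the lost (63) 223 and 99 to 252. H3K27me3 regions gained from 7 to 9 dpf (1379) were 423 with an equal number and 1847 to 3285 with 1 left out, and the lost (100) 291 and 183 to 562. From 5 to 9 dpf the gained (1497) were 518 and 1891 to 3412, and the lost (180) 386 and 276 to 658. From 5 to 7 dpf the gained (290) were 493 to 1018 and the lost (351) 543 to 1067. Leaving out a library relaxes the rule that both libraries of an age carry a peak, so its counts are higher by construction. Regions with both marks at 5 dpf (1355) were 2035 with a peak in any library of the age.

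Among counts and values 92 moved and 204 did not, where a count moved beyond 1.5 times and another value beyond the SD between replicates. Links of peaks to expression were not run, so their alternatives (a narrower and a wider window around the start of a gene, peaks in any library, an equal number of peaks) were not run either.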

Other observations

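Gene groups not yet described were looked at. They were chosen after the values were seen, as was cyclic loess scaling. Of the tests named below, the criteria for thinning, for the authors' size factors and for input background were set after the result. The other criteria were written before their tests. Of 15 replication-dependent histone genes 9 were lower at 7 than at 5 dpf (median log2 -1.30) and 5 were higher at 9 than at 7 dpf, and 0 passed from 5 to 9 dpf in limma. HIST2H3A went from 50.3 to 13.1 and 43.4 (n = 3 per age, 7 against 5 dpf adjusted p = 0.000711 in limma). Histone mRNA mostly lacks a poly(A) tail and is made in S phase, and near-identical copies share reads, so single copies are uncertain.

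Of 15 genes of class I antigen presentation and the immunoproteasome, 3 were higher at 7 than at 5 dpf, 4 at 9 than at 7 dpf and 10 at 9 than at 5 dpf (median log2 1.02), and the group as a whole was not tested. The light chain b2m went from 15.9 to 61.2 and 105 (9 against 5 dpf log2 2.67, adjusted p = 2.95e-05 in limma). The proteasome activator psme2 went from 177 at 7 dpf to 375 at 9 dpf (9 against 5 dpf 2.62, adjusted p = 9.59e-09), and psme1 went from 145 to 296 and 503 (1.81, adjusted p = 3.83e-06). Of 11 genes named mfap4 or MFAP4 (1 of many), 4 were higher at 9 than at 5 dpf. The copy named mfap4 itself, a gene of macrophages in zebrafish, was not among them. It was at 21.4 at 5 dpf and 18.6 at 9 dpf (log2 -0.20, adjusted p = 0.664 in limma).

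More genes were called higher than lower at 9 against 5 dpf, and the libraries of an age differ by a tilt, weak genes up and abundant genes down. The tilt, positive where weak genes are up, was 0.0365, 0.163 and 0.00209 in 5 dpf libraries 1 to 3. It was -0.0241, 0.0699 and -0.0899 at 7 dpf and 0.0117, -0.121 and -0.0473 at 9 dpf. It thus tended to run with age too, along the contrast it may explain, although the ages overlapped. After cyclic loess the share higher was 55.1%, but loess centres each library along abundance and so draws the share to balance whatever the cause, which is why the tilt and a true excess of rises cannot be told apart. With TMM in place of the authors' size factors the share was 67.3%, above the mark of 65 set after the result by less than the SD of 5.55 points over left-out libraries, so the size factors stay open too. Library depth was first tested by the correlation of the tilt with log10 total reads, and this met the criterion set for it as a cause (r = -0.909, rho = -0.933, permutation p = 0.0004 and 0.00086, the same adjusted by BH over 2 relations, r = -0.808 without the 2 farthest libraries, -0.864 for deviations from the age means, n = 9). A second test, chosen afterwards, thinned all libraries to the smallest, and 102% of the SD of the tilt remained, which excludes only depth acting through counting. The tilt also followed the share of odorant receptor reads (239 genes, r = 0.924, rho = 0.95, permutation p = 0.00013 and 0.00039, BH 0.00026 and 0.00078, r = 0.889 without the 2 farthest, 0.909 for deviations, n = 9), but all of these lie below the median abundance of the genes tested and so rise with the tilt by construction, and whether background reads spread over the genome are behind it stays open.

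Of 69 cell proliferation genes 16 passed lower from 5 to 7 dpf, 5 passed higher from 7 to 9 dpf and 11 had a higher second step. The tilt might have made this, but 100% of the members that passed the step contrast, 11 of 11, remained after cyclic loess. A single library might have made it, but the highest unadjusted camera p of the list in the contrast of steps with any library left out was 2.26e-06 with the preset correlation, although 4 members passed without 7dpf_1 and the list was not called with an estimated correlation (adjusted p = 0.442). Age itself, with first feeding and the days after it, stays open and untested.

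H3K27me3 regions were more numerous at 9 than at 5 dpf. A more sensitive peak list that adds weak peaks may be behind this: 29.8% of the gained regions, 446 of 1497, scored above the median of the 9 dpf lists, where under 25 was set as the mark for it and 40 or more as the mark against, so this cannot be told apart from new regions, the value lying between the marks, and peaks above the median score of all lists were 55.6% more numerous against 50.6% for all peaks. Background also seen in the input could add regions, and 98.2% of the gain was kept without regions that overlap input peaks. Only 0.371% to 0.974% of the peaks of an H3K27me3 library overlapped input peaks. Their removal could therefore change little, and it does not decide the question. For the idea that H3K27me3 appears where H3K4me3 is lost, 1 of 63 lost H3K4me3 regions (1.59%) gained H3K27me3 against 360 of 15548 kept ones (2.32%), a ratio of 0.686 with Fisher exact p = 1. The exact 95% interval of the share, added after the result was seen, is 0.0402% to 8.53%, up to a ratio of 3.68, so 63 regions are too few to tell.

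The 6 libraries of each pair of ages can be split 10 ways into 3 and 3, too few for a share under 0.05. In each pair 1 split of 10, the real one, gave as many genes past limma: 985, 458 and 4094 against at most 1, 49 and 0 in the others. For the contrast of steps 100 splits were counted, the real one and random ones. Of these 5, the real one included, gave at least the real 244, so chance is not excluded by this test. The highest gave 2910, and it set the 5 dpf libraries in the middle place against all others, so that split follows the structure of the samples.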
